A study of Mus musculus with 54 samples.

How the data were processed

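Early proximal tubules that stained for SGLT2 were cut from mouse kidney sections by laser capture, 70 to 80 tubules per sample, and their RNA was sequenced. Per the labels' protocols, stranded total RNA libraries were made with a SMARTer Pico kit from 0.5 ng of RNA with a DV200 above 30% (DV200 is the share of RNA fragments longer than a set length, a measure of RNA integrity). The deposited table holds TPM, a measure of transcript abundance in which every library is scaled to the same sum. Salmon and MultiQC 1.8 and the mouse genome build GRCm38 were named, per the submitters' processing notes. The Salmon version and the annotation release are not given in the sources used here.

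Of 54 labelled samples, 48 had a column in the table and 6 were not analysed here. Each group had 6 labelled samples. All 6 were in the table for both Akita vehicle groups and both knockout dapagliflozin groups. The other groups kept 5, or 4 in non-diabetic wild type with dapagliflozin. Comparisons with Akita vehicle tubules can therefore set groups that lost samples against a reference that lost none. The deposited table states in its name that outliers had been removed, by a rule not given in the sources used here. Removal of that kind can narrow the spread between the samples that remain, and so make p-values smaller. Columns were matched to samples by the capture number in the sample title, and groups were taken from the labels alone. The labels do not tie samples to animals, and replicate numbers only name samples, in the order of their records. P-values therefore measure only the spread between these samples, which may be partly technical, and are too small wherever samples share an animal.

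TPM keeps no sequencing depth, so the depth of each library is unknown and no counting error could be given. In the deposited TPM values 1 ribosomal RNA transcript took 36.8% to 64.4% of a library (median 49.2%), mitochondrial ribosomal RNA 14.2% to 31.7%, and nuclear protein-coding genes 5.98% to 14.1%. The gene Lars2 was left out of this protein-coding share, and of the sum used wherever TPM was rescaled to nuclear protein-coding genes. Since every library has the same sum, the TPM of a gene depends on the share left by other RNA, ribosomal RNA among it. The nuclear protein-coding share did not follow that 1 transcript in every library. It was 12.2% in non-diabetic knockout dapagliflozin sample 4, where the transcript took 61.4%. In non-diabetic knockout vehicle sample 1 it was 8.18%, where the transcript took 37.8%. Scaling factors by the median-of-ratios method ranged from 0.623 to 1.55. Between libraries, Pearson correlations over the tested genes ran from 0.841 to 0.945, and no pair of columns was identical.

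Of 55487 rows, 12742 genes with a TPM of at least 1 in at least 5 samples were tested, 10418 of them annotated as protein-coding. Zeros made up 5.24% of the tested values. Of 13307 rows named by an Ensembl identifier, 12844 were given the gene symbol of the reference name table, and 51909 rows matched the GENCODE annotation of GRCm38, which supplied positions. Values were analysed as log2(TPM + 1), on which scale fold changes of low genes are understated. A linear model with 9 groups was fitted to each gene with limma 3.58.1 in R 4.3.3, with 39 residual degrees of freedom and moderated variances (trended and robust, statmod 1.5.0). Two-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene is from this limma model. An SE is that of the model, and an SD is that of TPM between samples.

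The design, the 14 comparisons and 7 correlations, 46 gene lists with 799 genes and the rule for naming genes were fixed before the data were examined. The lists cover tubule segment identity, transport, metabolism, stress, signalling and inflammation, and other kidney and blood cell types. Each list was tested against all other genes with camera on the moderated statistics at a preset correlation between genes of 0.01, adjusted over the 46 lists of a comparison, and again with a correlation estimated from the residuals. A list's size of change is the median log2 fold change of its members less the median of all tested genes. Counts of members higher, lower or called go by each gene's own change and are not taken relative to all genes. A shift of all genes therefore moves these counts. Its median was 0.17 for dapagliflozin in Akita averaged over genotypes and 0.32 for the interaction of dapagliflozin with diabetes. In addition, 4 comparisons that average effects over genotypes or backgrounds were chosen after the data were seen. A further average, the interaction of dapagliflozin with diabetes over both genotypes, was tried, called 0 genes by limma and was dropped.

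The text names genes by a rule that left out predicted genes, clones and pseudogenes. From each comparison it took the 10 largest rises and 10 largest falls among called genes with a mean TPM of at least 5 in the higher group, up to 4 called members of each list, and always the glucose transporters and Glp1r. With fewer than 6 called genes it also took the 3 highest and 3 lowest by moderated statistic at that TPM (ranks in the text are of this order), and from each list past the set test up to 4 members with the smallest p. The text names part of what the rule allows. Gm42047, Gm43694, Sox5 and Npl fall outside the rule and were named after their values were seen.

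The script was tested on simulated data with the real genes' means and spread. Changes were planted only in genes averaging above about 5 TPM, and noise was drawn independently for each gene. Real libraries also differ in ways shared by many genes, so the shares below may not hold for low genes or for these data. For diabetes in wild-type tubules it recovered 8%, 60%, 92% and 96% of 50 genes each changed 1.5, 2, 3 and 4 fold, with 9 unchanged genes called. For dapagliflozin in Akita tubules averaged over genotypes the shares were 42%, 86%, 98% and 98%, with 7 unchanged genes called. Alternatives were another pseudocount, 2 other filters on low values, quantile and median-of-ratios scaling, fits of the compared groups alone, sample weights, the capture number or the number of genes detected as a covariate, and leaving out each library in turn. TPM rescaled to nuclear protein-coding genes, the 4 libraries with fewest genes left out, and the estimated correlation on median-of-ratios values were added after the data were seen. Python 3.11.15 with matplotlib 3.10.9 drew the figures.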

Results

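RNA was measured in SGLT2-positive early proximal tubules, the first part of the nephron after the glomerulus, where SGLT2 takes up most of the filtered glucose. The tubules came from male DBA mice aged 14 weeks. Non-diabetic mice were compared with Akita mice, whose Ins2 mutation causes insulin-deficient diabetes. Both carried either wild-type or knocked-out Sglt1, the second glucose transporter of the tubule, encoded by Slc5a1. Mice received vehicle or the SGLT2 inhibitor dapagliflozin (10 mg/kg diet) for 2 weeks. A further group of Akita wild-type mice received semaglutide, a GLP-1 receptor agonist, at 3 nmol/kg per day. In the table, non-diabetic mice gave 5 wild-type vehicle, 5 knockout vehicle, 4 wild-type dapagliflozin and 6 knockout dapagliflozin samples. Akita mice gave 6 wild-type vehicle, 6 knockout vehicle, 5 wild-type dapagliflozin, 6 knockout dapagliflozin and 5 wild-type semaglutide samples.

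Between 8465 and 11419 genes were detected per library at a TPM of 1 or more (median 10116). Means were lower in Akita vehicle tubules, at 9665 ± 812 genes in wild type (SD, n = 6) and 9686 ± 1062 in knockouts (n = 6), than in non-diabetic vehicle tubules, at 10166 ± 577 (n = 5) and 10487 ± 746 (n = 5). The 4 libraries with fewer than 9000 genes were 2 Akita wild-type vehicle and 2 Akita knockout vehicle samples. All semaglutide samples had capture numbers from 88 to 99, while the numbers of Akita wild-type vehicle samples ran from 1 to 82. Those of non-diabetic wild-type vehicle samples, the reference for diabetes in wild type, ran only from 54 to 84. The other groups held wider ranges, such as 11 to 72 in non-diabetic wild type and 9 to 98 in non-diabetic knockouts with dapagliflozin. The number was also tried as a covariate.

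**Figure D1:**
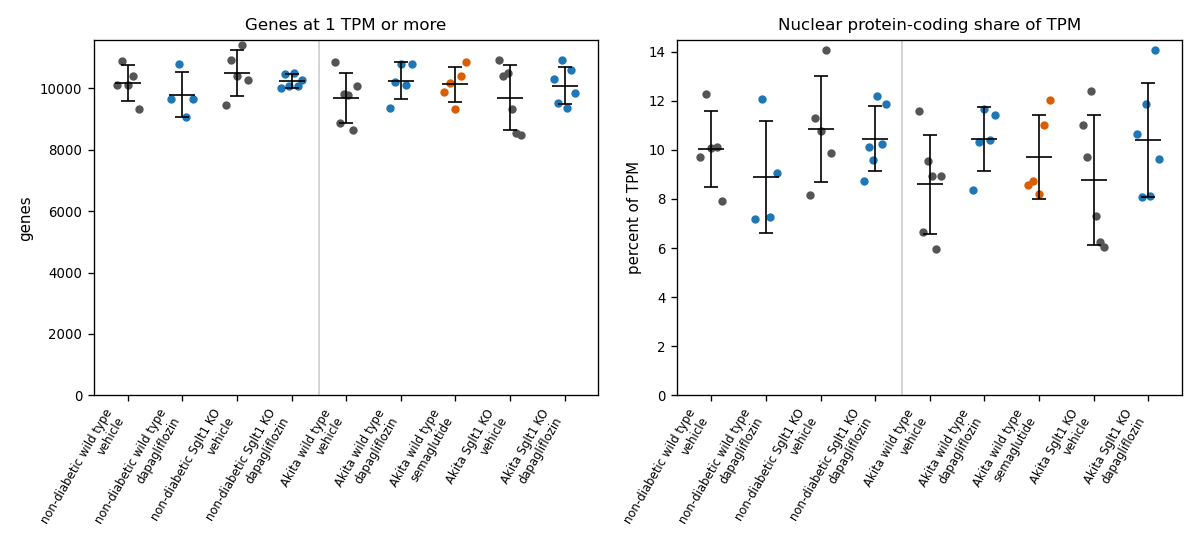
Genes detected at a TPM of 1 or more (left panel) and the percentage of TPM from nuclear protein-coding genes other than Lars2 (right panel), 1 point per library in each of 9 groups, with bars for the mean and SD. The 4 libraries below 9000 genes are all Akita vehicle samples.

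The Sglt1 target was examined first. Slc5a1 (chromosome 5, 33104219 to 33162870, GRCm38) lay between 0.814 and 4.29 TPM in all 25 wild-type libraries (2.04 ± 0.941, SD). It lay between 0 and 0.123 TPM in all 23 knockout libraries (0.0252 ± 0.0371), so no library went against its labelled genotype. Slc5a2, which encodes SGLT2 and by whose product the tubules were chosen, ranged from 82.5 to 275 TPM and was called in no comparison of the deposited TPM. Its log2 change was 0.15 ± 0.26 (SE) with diabetes in wild type (adjusted p = 0.919, above the non-diabetic median in 5 of 6 samples) and −0.14 ± 0.26 in knockouts (adjusted p = 0.81, below it in 3 of 6), values that became 0.38 and 0.21 with median-of-ratios scaling (adjusted p = 0.49 and 0.783). With dapagliflozin in Akita wild type it was −0.41 ± 0.26 (adjusted p = 0.604, below the vehicle median in 4 of 5), and −0.69 with median-of-ratios scaling (adjusted p = 0.186). Averaged over both Akita genotypes it was −0.30 ± 0.18, and it was called as lower with 3 other scalings. These were quantile normalization (−0.64, adjusted p = 0.0329), median-of-ratios scaling (−0.56, adjusted p = 0.0133) and TPM rescaled to nuclear protein-coding genes (−0.59, adjusted p = 0.00941). Over all knockout backgrounds the change was 0.08 ± 0.13 for Slc5a2 (adjusted p = 0.943, 15 of 23 samples above the wild-type median). That of Slc2a2, which encodes the basolateral glucose transporter GLUT2, was 0.05 ± 0.13 (adjusted p = 0.965, 11 of 23), and both turned slightly negative with median-of-ratios scaling (−0.01 and −0.04). Glp1r, the receptor of semaglutide, stayed at or below 0.277 TPM in every library and was too low to test.

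**Figure D2:**
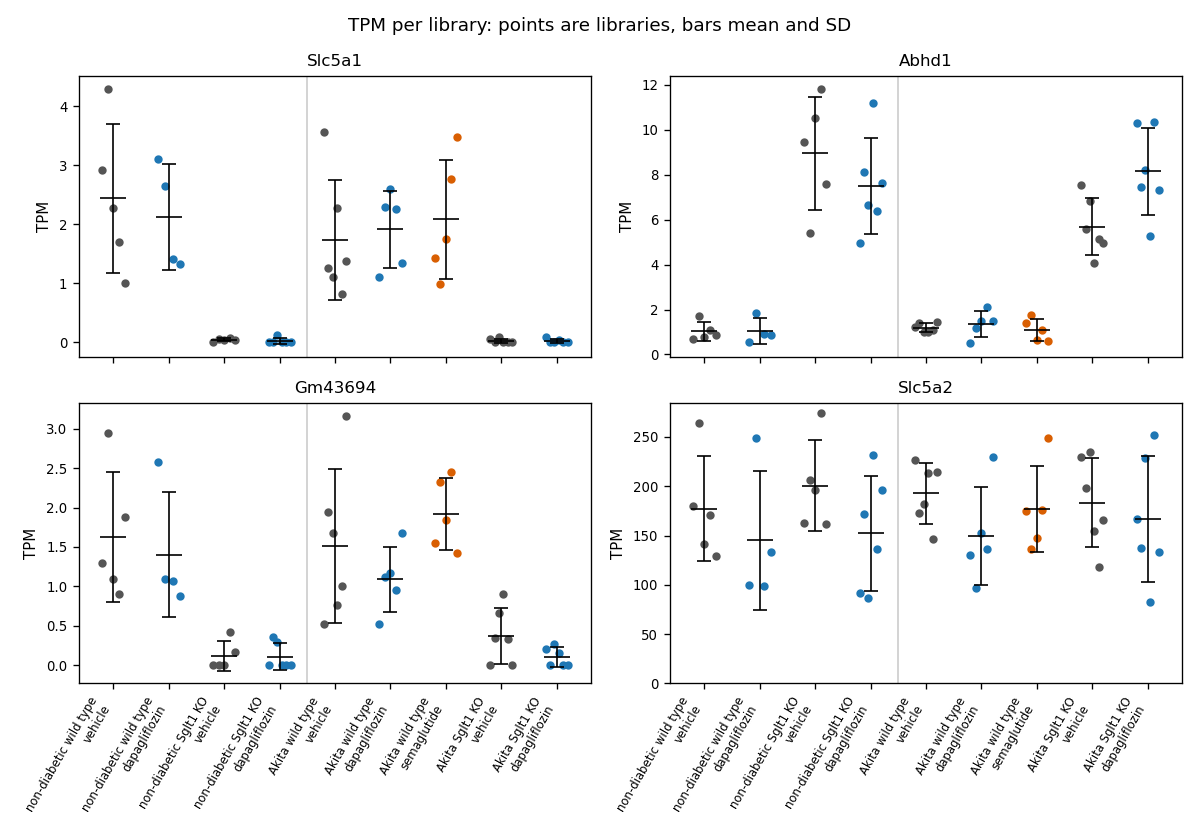
TPM of Slc5a1, Abhd1, Gm43694 and Slc5a2 in each library of the 9 groups, with bars for the mean and SD. Slc5a1 lies at 0.123 TPM or below in every knockout library, and Abhd1 at 4.09 TPM or above.

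Diabetes in wild-type tubules raised Apob, the structural protein of chylomicrons and low-density lipoprotein, from 1.60 ± 0.511 TPM (SD, n = 5) to 9.66 ± 3.78 TPM (n = 6), a log2 change of 1.97 ± 0.38 (SE). Car3, a carbonic anhydrase, fell by 2.39 ± 0.47, from 7.08 ± 4.44 to 0.371 ± 0.324 TPM. The predicted gene Gm42047 (chromosome 8, 121833247 to 121841178), singled out after its values were seen, rose by 2.41 ± 0.44. Genes that in mouse kidney are induced by androgen or higher in males fell as a list, with all 12 tested members lower and a median 0.75 below that of all genes. Kap, the kidney androgen-regulated protein, averaged 1852 ± 370 TPM in non-diabetic and 973 ± 291 TPM in Akita tubules. The cytochrome P450 genes Cyp2e1 (177 ± 22.4 against 83.8 ± 34.4 TPM) and Cyp4a12a (59.2 ± 17.9 against 26.3 ± 8.51 TPM) lay lower in 6 of 6 Akita samples than the non-diabetic median.

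These 3 genes, 2 higher and 1 lower, were the ones called by limma among 12742 (969 at an unadjusted p under 0.05), with adjusted p of 0.0242 for Apob, 0.0316 for Car3 and 0.0242 for Gm42047, each in the same direction in 6 of 6 Akita samples. Next by rank, and not called, were Adam11, a member of the disintegrin family (1.72 ± 0.37, adjusted p = 0.0627, 6 of 6 samples higher), Inmt, a methyltransferase (−1.21 ± 0.26, adjusted p = 0.0627, 6 of 6 lower), and Ldhd, D-lactate dehydrogenase (−1.12 ± 0.25, adjusted p = 0.108, 6 of 6 lower). The median of all genes was −0.15, a shift that median-of-ratios scaling removed. With that scaling 12 genes were called, 7 higher and 5 lower, and with TPM rescaled to nuclear protein-coding genes 11, 6 higher and 5 lower. Leaving out 1 library gave 0 calls (non-diabetic vehicle samples 1, 3 or 6, or Akita vehicle sample 6), 1 (non-diabetic vehicle sample 5), 5 (Akita vehicle sample 3) or 6 (Akita vehicle sample 1). Without the 4 libraries with fewest genes only Apob was called. The same held with the capture number as a covariate, where Car3 had an adjusted p of 0.136 and Gm42047 of 0.0511. With no filter 0 genes were called.

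**Figure D3:**
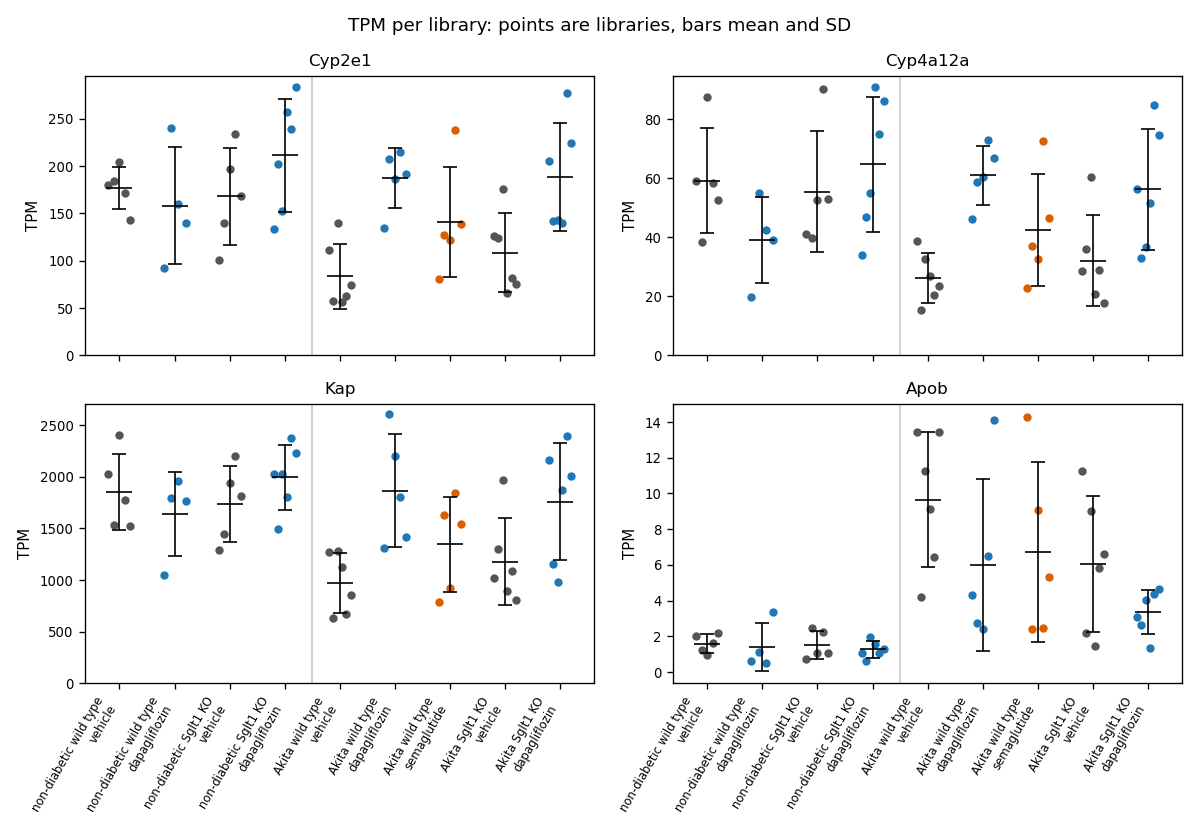
TPM of Cyp2e1, Cyp4a12a, Kap and Apob in each library of the 9 groups, with bars for the mean and SD. Cyp2e1 averaged 177 TPM in non-diabetic wild-type vehicle tubules, 83.8 TPM in Akita wild-type vehicle tubules and 187 TPM in Akita wild-type tubules with dapagliflozin.

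Of 46 lists, 19 passed the camera test with the preset correlation (3 higher, 16 lower). The male-biased list had an adjusted p of 4e-14, with 9 of 12 members lower when adjusted over the list alone and 0 over all genes. It alone passed with an estimated correlation (adjusted p = 0.0387). Late proximal tubule (S3) markers, 3 of which are also on the male-biased list, had all 10 members lower (median 0.73 below all genes, 7 called when adjusted over the list alone), among them the organic anion transporter Slco1a1 (−1.38 ± 0.36) and the amino acid transporter Slc7a13 (−1.16 ± 0.31). Their adjusted p was 1.04e-07, and 0.267 with an estimated correlation. Drug and steroid metabolism, which shares 4 genes with the male-biased list, had 18 of 19 members lower (−0.53 from all genes, adjusted p = 9.9e-08, and 0.562 with an estimated correlation). Adjusted over the list alone 10 were lower and 1 higher. Fatty acid synthesis was lower (−0.27, adjusted p = 0.0105, 12 of 13 members and 4 over the list alone, and 0.848 with an estimated correlation), with Scd1 at −1.27 ± 0.34 and Fasn at −0.69 ± 0.22. So were organic anion, organic cation and urate transporters (−0.22, adjusted p = 0.00345, 17 of 20 members and 3 over the list alone, and 0.848 with an estimated correlation). Markers of neighbouring structures moved as well. Thick ascending limb markers were lower (−0.45, 7 of 7 members, 2 over the list alone, adjusted p = 0.000664, and 0.623 with an estimated correlation), with Umod at −1.26 ± 0.44 and Slc12a1 at −1.29 ± 0.38. Their list value was −0.94 with a pseudocount of 0.1, −1.07 with the stricter filter and −1.01 with TPM rescaled to nuclear protein-coding genes. Podocyte markers were higher (0.34, 5 of 8 members, 0 over the list alone, adjusted p = 0.0116, and 0.848 with an estimated correlation), a call lost without non-diabetic vehicle sample 5 (adjusted p = 0.0531) or Akita vehicle sample 1 (adjusted p = 0.0534). It was also lost with median-of-ratios scaling (adjusted p = 0.109), and that of fatty acid synthesis without the 4 libraries with fewest genes (adjusted p = 0.0648).

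In Sglt1 knockout tubules, diabetes called 0 genes by limma, with 1836 at an unadjusted p under 0.05 and a median of all genes of −0.24. Apob was 1.33 ± 0.38 (adjusted p = 0.2, higher than the non-diabetic median in 6 of 6 samples) and Adam11 1.37 ± 0.37 (adjusted p = 0.192, 6 of 6). The lowest by rank were Cdo1, cysteine dioxygenase (−1.21 ± 0.28), and the organelle biogenesis genes Hps1 (−1.38 ± 0.32) and Bloc1s1 (−0.82 ± 0.18), each with an adjusted p of 0.14 and 6 of 6 samples lower. The third highest was the ribosomal protein gene Rps15a (1.07 ± 0.40, adjusted p = 0.293, 6 of 6). Of 46 lists, 7 passed with the preset correlation and 0 with an estimated one. Immediate early and heat shock genes fell, with 18 of 19 members lower (−0.37 from all genes, adjusted p = 0.000238, and 0.994 with an estimated correlation). Of them 7 were called over the list alone, including the heat shock proteins Hspa1a (−1.52 ± 0.36) and Hspa1b (−1.63 ± 0.49). Without non-diabetic knockout vehicle sample 2 the list value shrank to −0.16 (adjusted p = 0.0114). The male-biased list was lower (−0.34, 11 of 12 members, 6 over the list alone, adjusted p = 0.0202), as were ER stress genes (−0.25, 15 of 17, 5 over the list alone, adjusted p = 0.0202) and endothelial markers (−0.31, 11 of 11, 0 over the list alone, adjusted p = 0.0121). Each of these had an adjusted p of 0.994 with an estimated correlation, and each lost its call without some single libraries. For the male-biased list these were non-diabetic knockout vehicle samples 3, 5 or 6 and Akita knockout vehicle samples 1 or 4 (adjusted p up to 0.0946). For ER stress they were non-diabetic samples 2 or 3 and Akita samples 1 or 4 (up to 0.336), besides median-of-ratios scaling (0.051). For endothelial markers they were non-diabetic sample 2 or Akita sample 5 (up to 0.0833). Endothelial markers also lost it without the 4 libraries with fewest genes (adjusted p = 0.254).

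The difference between the diabetes effects in knockout and wild type was tested as an interaction, which called 0 genes by limma (406 at an unadjusted p under 0.05). Of 46 lists, 15 passed with the preset correlation and 0 with an estimated one. The median of all genes was −0.08. Thick ascending limb markers (0.73 from all genes, 7 of 7 members higher, adjusted p = 0.00231) and the male-biased list (0.45, 11 of 12, adjusted p = 0.00378) had higher signed values in the knockout effect, a smaller fall for the latter. Podocyte markers (−0.46, 8 of 8 lower, adjusted p = 0.00635) and immediate early and heat shock genes (−0.40, 17 of 19, adjusted p = 0.00358) had lower ones. With an estimated correlation the adjusted p was 0.853 for each, and adjusted over the list alone each had 0 called members. The value of thick ascending limb markers was 0.45 with no filter and 1.19 to 1.22 with a pseudocount of 0.1, the stricter filter or nuclear rescaling. That of podocyte markers was −0.92 with the pseudocount or the rescaling. Without non-diabetic wild-type vehicle sample 4 the value of the immediate early and heat shock genes was −0.23 (adjusted p = 0.0135). The male-biased list lost its call without the 4 libraries with fewest genes (adjusted p = 0.0566).

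Averaged over both genotypes, a comparison chosen after the data were seen, diabetes raised Apob by 1.65 ± 0.27, Adam11 by 1.55 ± 0.26 and Npl, the sialic acid lyase, by 0.90 ± 0.19, each above the non-diabetic median in 12 of 12 Akita samples. It lowered Car3 (−2.12 ± 0.33), Cdo1 (−1.10 ± 0.20), Ldhd (−0.95 ± 0.18) and Cyp2e1 (−0.90 ± 0.19) in 12 of 12 samples, and Cyp4a12a (−0.99 ± 0.21) and Kap (−0.78 ± 0.18) in 11 of 12. Other called falls were those of the lysophospholipid transporter Mfsd2a (−1.73 ± 0.42), the peroxisomal hydrolase Nudt19 (−1.32 ± 0.30), Cyp2d12 (−1.23 ± 0.29), Slco1a1 (−1.14 ± 0.25), angiotensin-converting enzyme Ace (−1.05 ± 0.25), Slc7a13 (−0.87 ± 0.22), Hsd17b11 (−0.83 ± 0.21), the urate transporter Slc17a3 (−0.65 ± 0.16) and the chaperones Hsp90aa1 (−0.77 ± 0.17), Hspa5 (−0.68 ± 0.16) and Pdia6 (−0.67 ± 0.17). In all, limma called 71 genes, 3 higher and 68 lower, with 2360 at an unadjusted p under 0.05. Adjusted p among those named ran from 0.000854 for Apob and Car3 to 0.0488 for Slc7a13 and Hsd17b11. Slc5a2 was 0.01 ± 0.19, and 0.29 with median-of-ratios scaling (adjusted p = 0.333).

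Most of these calls depended on scaling, covariates, the filter and single libraries. With the capture number as a covariate 17 genes were called, 3 higher and 14 lower, and 9 with the number of genes detected. With no filter the count was 18, and 30 in a fit of only the groups compared. The median of all genes was −0.20, and with median-of-ratios scaling 22 genes were called, 12 higher and 10 lower, with 7 of the 20 named genes among them. Without the 4 libraries with fewest genes 4 genes were called, Apob (adjusted p = 0.00536), Adam11 (0.0238), Car3 (0.0338) and Cdo1 (0.0338). Leaving out 1 library at a time gave 11 to 313 calls and moved the count by over 1.5 times for every library except non-diabetic wild-type vehicle sample 3, Akita wild-type vehicle sample 3 and Akita knockout vehicle sample 2. Apob, Adam11, Car3, Cdo1, Ldhd and Npl were called without any single library, and the other 14 named genes lost their call without 2 to 15 of the 22.

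The male-biased list had all 12 members lower in this average (−0.57 from all genes, adjusted p = 3.27e-11), 5 called over all genes and 11 over the list alone, with an adjusted p of 0.133 with an estimated correlation. S3 markers were lower (−0.49, 10 of 10 members, 2 called and 8 over the list alone, adjusted p = 2.34e-05, and 0.613 with an estimated correlation). So was drug and steroid metabolism (−0.30, 18 of 19, 3 called and 14 lower and 1 higher over the list alone, adjusted p = 6.38e-05, and 0.967 with an estimated correlation). ER stress genes were lower (−0.25, 15 of 17, 2 called and 11 over the list alone, adjusted p = 0.0013, and 0.967 with an estimated correlation). Fatty acid synthesis reached an adjusted p of 0.0482 (−0.12, 12 of 13 members lower, 4 over the list alone, and 0.967 with an estimated correlation), and lost it without any of 13 single libraries and without the 4 with fewest genes (adjusted p = 0.166).

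In non-diabetic tubules Abhd1, an alpha/beta hydrolase, was higher in Sglt1 knockouts, at 8.96 ± 2.52 TPM (SD, n = 5), than in wild type, at 1.03 ± 0.421 TPM (n = 5), a log2 difference of 2.28 ± 0.22 (adjusted p = 4.5e-10). Slc5a1 fell by 1.64 ± 0.22 (adjusted p = 7.6e-06). The predicted gene Gm43694 fell by 1.19 ± 0.22 (adjusted p = 0.0115), and all 3 differed in 5 of 5 samples. In Akita tubules the same direction was seen for Abhd1 (1.59 ± 0.20, adjusted p = 1.89e-06) and Slc5a1 (−1.34 ± 0.20, adjusted p = 0.000123), in 6 of 6 samples each. Gm43694 was not called there. Over all backgrounds Abhd1 lay between 4.09 and 11.8 TPM in the 23 knockout libraries and between 0.521 and 2.12 TPM in the 25 wild-type ones. Abhd1 (chromosome 5, 30950066 to 30955091) and Gm43694 (chromosome 5, 32629842 to 32630960) lie on the same chromosome as Slc5a1, and Abhd1 overlaps Preb (30950853 to 30960361) on the other strand.

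These were the calls of limma among all genes, 1 higher and 2 lower in non-diabetic tubules (587 at an unadjusted p under 0.05) and 1 higher and 1 lower in Akita (249). Gm43694 lost its call in non-diabetic tubules without wild-type vehicle samples 3 or 6 or knockout vehicle samples 1 or 3 (adjusted p up to 0.2). In non-diabetic tubules the highest by rank after Abhd1 were Anapc4 (0.91 ± 0.24, adjusted p = 0.751) and Med15 (1.02 ± 0.29, adjusted p = 0.981), above the wild-type median in 5 of 5 samples. The lowest after Slc5a1 were Fdx1 (−0.74 ± 0.24) and Hibch (−0.97 ± 0.35), both at an adjusted p of 0.981 and below it in 5 of 5. In Akita they were Cd36, the fatty acid translocase (1.01 ± 0.29), Stt3a (1.45 ± 0.43) and Timm50 (−0.86 ± 0.24), with an adjusted p of 1 and 6 of 6 samples in that direction. The glucose transport list holds the targeted gene itself, Slc5a1, its 1 called member. With it the list passed in non-diabetic tubules (−0.21 from all genes, 8 of 10 members lower, adjusted p = 0.000374, and 0.753 with an estimated correlation). It also passed in Akita (−0.15, 6 of 10, adjusted p = 0.0349, and 0.988 with an estimated correlation), though not without knockout vehicle sample 2 (adjusted p = 0.0583) or 5 (0.0502). Without Slc5a1, a check added after the results were seen, it passed in neither (−0.17, 7 of 9 lower, adjusted p = 0.107, and −0.11, 5 of 9 lower, adjusted p = 0.58). In non-diabetic knockouts nuclear-encoded oxidative phosphorylation was lower (−0.22, 41 of 52 members, 0 called over the list alone, adjusted p = 1.17e-05, and 0.753 with an estimated correlation). The lists past the preset test numbered 20 in non-diabetic and 6 in Akita tubules, and 0 with an estimated correlation.

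Averaged over 4 backgrounds, a comparison chosen after the data were seen, the knockout again called Abhd1 (1.97 ± 0.11, adjusted p = 6.34e-20), Slc5a1 (−1.51 ± 0.11, adjusted p = 4.18e-15) and Gm43694 (−1.0 ± 0.11, adjusted p = 1.54e-08), each in 23 of 23 knockout samples and without any single library. With median-of-ratios scaling 5 genes were called, 1 higher and 4 lower. The count was 5 without Akita wild-type vehicle sample 1 or Akita knockout vehicle sample 6. Cd36 (0.70 ± 0.15, 21 of 23 samples higher) and Irf7, an interferon regulatory factor (0.60 ± 0.13, 20 of 23), were not called (adjusted p = 0.0849 each). Antigen presentation genes were higher (0.24 from all genes, 15 of 15 members, 0 over the list alone, adjusted p = 2.55e-05, and 0.895 with an estimated correlation). So were interferon response genes (0.13, 12 of 14, 3 over the list alone, adjusted p = 0.00355, and 0.895 with an estimated correlation). The glucose transport list passed in the downward direction with Slc5a1, its 1 called member (adjusted p = 4.82e-05, and 0.772 with an estimated correlation), although 7 of 10 members were higher and its median was 0.04. Without Slc5a1 the adjusted p was 0.94, with a median 0.02 below all genes and 7 of 9 members higher.

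Dapagliflozin in Akita wild-type tubules called 0 genes by limma, with 1289 at an unadjusted p under 0.05 and a median of all genes of 0.19. Kap (973 ± 291 TPM with vehicle, SD, n = 6, and 1867 ± 543 TPM with dapagliflozin, n = 5), Cyp2e1 (83.8 ± 34.4 and 187 ± 31.7 TPM) and Cyp4a12a (26.3 ± 8.51 and 61 ± 9.95 TPM) lay above the vehicle median in 5 of 5 treated samples, with adjusted p of 0.22, 0.187 and 0.2. The highest by rank were Arpp19, a phosphatase regulator (1.03 ± 0.21, adjusted p = 0.132), Cyp2e1 (1.22 ± 0.27) and Abcd3, a peroxisomal fatty acid transporter (0.89 ± 0.20, adjusted p = 0.187), each in 5 of 5. Among the lowest were Palm3, a paralemmin (−0.79 ± 0.27, adjusted p = 0.319, 5 of 5 lower), and cyclin D1, Ccnd1 (−0.72 ± 0.30, adjusted p = 0.401, 4 of 5). Without Akita wild-type vehicle sample 1 the count was 5, with Arpp19 and Abcd3 (adjusted p = 0.0205 each) and Cyp2e1 (0.0488) among them. It was 4 without dapagliflozin sample 1 and 1 without dapagliflozin sample 5, and with TPM rescaled to nuclear protein-coding genes it was 2, both higher.

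The male-biased list rose with dapagliflozin in Akita wild type, with 12 of 12 members higher (0.60 from all genes, adjusted p = 5.08e-09, and 0.342 with an estimated correlation). Of them 7 were called over the list alone. Drug and steroid metabolism was higher (0.44, 18 of 19 members, adjusted p = 8.87e-06), as were S3 markers (0.51, 10 of 10, adjusted p = 0.000699), fatty acid oxidation (0.26, 22 of 25, adjusted p = 6.47e-05), organic anion, cation and urate transporters (0.26, 17 of 20, adjusted p = 0.000203) and NRF2 and oxidative stress genes (0.17, 20 of 22, adjusted p = 0.000935). Podocyte markers were lower (−0.40, 5 of 8, adjusted p = 0.00937). With an estimated correlation the adjusted p was 0.679 for each of these 6. Members higher over the list alone numbered 9, 4, 6, 8, 4 and 0 in the same order, with 1 lower in drug and steroid metabolism. Fatty acid oxidation (adjusted p = 0.0883) and NRF2 genes (0.0681) lost their call without the 4 libraries with fewest genes, and podocyte markers without dapagliflozin sample 1 (0.0895) or with median-of-ratios scaling (0.0808). In all 15 lists passed, 10 higher and 5 lower, and 0 with an estimated correlation.

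In Akita knockout tubules dapagliflozin also called 0 genes by limma (967 at an unadjusted p under 0.05, median of all genes 0.15). Guca2b, which encodes uroguanylin, was 1.05 ± 0.26, the folate transporter Slc19a1 0.80 ± 0.19 and Hps1 1.28 ± 0.30, each above the vehicle median in 6 of 6 samples, and Palm3 was −1.13 ± 0.26, below it in 6 of 6, all at an adjusted p of 0.452. Cyp2e1 (0.83 ± 0.26) and Cyp4a12a (0.82 ± 0.28) were above it in 6 of 6 at an adjusted p of 0.643. With median-of-ratios scaling 3 genes were called, all lower, and leaving out knockout dapagliflozin sample 4 gave 1. Of 46 lists 10 passed, all higher, and 0 with an estimated correlation. They included the TCA cycle (0.22 from all genes, 19 of 20 members, adjusted p = 0.000117), drug and steroid metabolism (0.30, 18 of 19, adjusted p = 0.000211), the male-biased list (0.32, 12 of 12, adjusted p = 0.000243), organic anion, cation and urate transporters (0.18, 19 of 20, adjusted p = 0.000265) and NRF2 genes (0.18, 22 of 22, adjusted p = 0.000783). Adjusted over the list alone 2 members of each were higher, and 0 of the NRF2 list. With an estimated correlation the adjusted p was 0.998 for each. The dapagliflozin effects in knockout and wild type were compared directly, and the interaction called 0 genes by limma (246 at an unadjusted p under 0.05) and 0 lists.

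Averaged over both genotypes, again chosen after the data were seen, dapagliflozin in Akita tubules raised the cytochrome P450 genes Cyp4a12a (1.03 ± 0.20) and Cyp2e1 (1.02 ± 0.19), the carboxylesterase Ces2c (1.00 ± 0.21) and Guca2b (0.93 ± 0.19) in 11 of 11 treated samples. It raised Ace (0.99 ± 0.25) in 10 of 11 and the glutamine transporter Slc38a3 (0.99 ± 0.24) in 9 of 11. Further rises were those of Ugdh (0.96 ± 0.22), lipoprotein lipase Lpl (0.93 ± 0.22), Chp1 (0.91 ± 0.20) and the gluconeogenic enzyme Pck1 (0.89 ± 0.22), each in 11 of 11. Palm3 fell by 0.96 ± 0.19 in 10 of 11 and Npl by 0.81 ± 0.19 in 11 of 11 samples. In all limma called 104 genes, 102 higher and 2 lower (2225 at an unadjusted p under 0.05), with adjusted p among those named from 0.0157 for Cyp2e1 to 0.0467 for Slc13a3 and Gclc. Slc5a2 was −0.30 ± 0.18 (adjusted p = 0.39, lower in 8 of 11), and −0.56 with median-of-ratios scaling (adjusted p = 0.0133).

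Most of the 104 calls depended on the samples fitted, the filter, scaling and single libraries. A fit of only the groups compared called 3 genes, 2 higher and 1 lower. With no filter 6 were called, 5 higher and 1 lower, and with the number of genes detected as a covariate 34. The median of all genes was 0.17, and with median-of-ratios scaling 54 genes were called, 31 higher and 23 lower, with 9 of the 26 named genes among them. Without the 4 libraries with fewest genes 0 genes were called by limma, Cyp2e1 then standing at 0.83 (adjusted p = 0.228) and Palm3 at −0.99 (adjusted p = 0.228). Leaving out 1 library at a time gave 9 to 378 calls and moved the count by over 1.5 times for every library except Akita knockout vehicle sample 2 and Akita knockout dapagliflozin sample 3. Cyp2e1, Cyp4a12a, Guca2b, Palm3 and Slc17a1 were called without any single library, and the other 21 named genes lost their call without 3 to 15 of the 23.

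The male-biased list had 12 of 12 members higher (0.45 from all genes, adjusted p = 9.8e-10, and 0.251 with an estimated correlation), 3 called and 10 over the list alone, among them Kap (0.76 ± 0.17). Drug and steroid metabolism (0.35, 18 of 19, adjusted p = 9.14e-08) had 4 called members, including the glucuronosyltransferase Ugt3a2 (0.69 ± 0.17), and 14 higher and 1 lower over the list alone. Organic anion, cation and urate transporters (0.24, 18 of 20, adjusted p = 2.12e-06) had 4 called, Slc17a1 (0.82 ± 0.17), Slc17a3 (0.72 ± 0.16), Slc13a2 (0.77 ± 0.18) and Slc13a3 (0.69 ± 0.18), and 10 over the list alone. Fatty acid oxidation (0.24, 24 of 25, adjusted p = 2.12e-06) had 2 called, Etfdh (0.58 ± 0.14) and Acsm2 (0.60 ± 0.15), and 15 over the list alone. The TCA cycle (0.20, 20 of 20, adjusted p = 2.2e-06) had 0 called and 12 over the list alone. NRF2 and oxidative stress genes (0.18, 22 of 22, adjusted p = 1.26e-05) had 4 called, Gstm1 (0.81 ± 0.19), Gstp1 (0.75 ± 0.19), Gclc (0.61 ± 0.16) and Sod1 (0.54 ± 0.13), and 7 over the list alone. S3 markers (0.43, 10 of 10, adjusted p = 0.000454) had 0 called and 5 over the list alone, and the renin-angiotensin system (0.23, 9 of 9, adjusted p = 0.00473) had 1 called, Ace, and 5 over the list alone. Its value was 0.12 without wild-type dapagliflozin sample 5 (adjusted p = 0.00915) and 0.14 without knockout dapagliflozin sample 4 (0.00801). With an estimated correlation the adjusted p was 0.547 or 0.619 for each of these 7 lists. Ketohexokinase Khk (0.52 ± 0.13) and the sterol synthesis gene Nsdhl (0.63 ± 0.16) were also called.

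**Figure D4:**
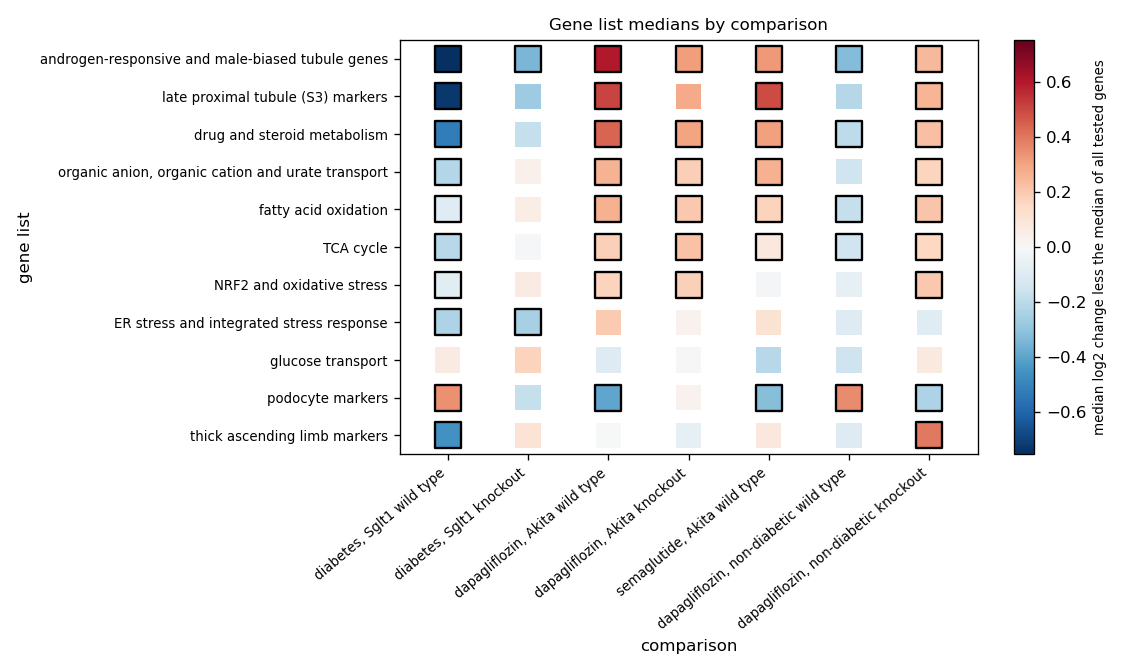
Median log2 fold change of selected gene lists less the median of all tested genes (colour), with a black frame where the adjusted p of camera with the preset correlation was under 0.05. Only the effects of diabetes, dapagliflozin and semaglutide against their reference groups are drawn. The knockout comparisons, the direct comparison of the drugs, the interactions and the averages are not. The male-biased list is at −0.75 with diabetes in wild type and at 0.60 with dapagliflozin in Akita wild type.

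Loss of Sglt1 combined with dapagliflozin was compared with Akita wild-type vehicle tubules, that is, Akita knockout mice given the SGLT2 inhibitor against Akita wild-type mice given vehicle. Glucose transport itself is not part of these data. Abhd1 rose by 2.04 ± 0.20 (adjusted p = 8.61e-10), Cd36 by 1.41 ± 0.29 (from 23.4 ± 10.9 to 63.5 ± 25.9 TPM, n = 6 and 6, adjusted p = 0.0196), Guca2b by 1.28 ± 0.26 (from 18.9 ± 6.09 to 48.8 ± 21.1 TPM, adjusted p = 0.0196), Cyp2e1 by 1.20 ± 0.26 (adjusted p = 0.0349) and the urate and phosphate transporter Slc17a1 by 1.08 ± 0.23 (adjusted p = 0.0349). Palm3 fell by 1.4 ± 0.26 (from 16.5 ± 3.5 to 5.72 ± 1.87 TPM, adjusted p = 0.00634), Slc5a1 by 1.35 ± 0.20 (adjusted p = 0.000116) and Gm43694 by 1.11 ± 0.21 (adjusted p = 0.00634). Each lay on that side of the vehicle median in 6 of 6 samples, and these 8 genes, 5 higher and 3 lower, were all that limma called (1358 at an unadjusted p under 0.05, median of all genes 0.16). With median-of-ratios scaling 44 genes were called, 25 higher and 19 lower, including these 8. Without the 4 libraries with fewest genes 4 were called, Abhd1, Slc5a1 and Palm3 (adjusted p = 0.0414) among them, while Cd36 (0.439), Guca2b (0.271), Cyp2e1 (0.439), Slc17a1 (0.48) and Gm43694 (0.0547) were not. Leaving out 1 library moved the count by over 1.5 times for 11 of 12. It was 3 to 5 without Akita wild-type vehicle samples 2, 4, 5 or 6 or knockout dapagliflozin samples 1, 5 or 6, and 13 to 26 without vehicle samples 1 or 3 or dapagliflozin samples 2 or 4. Abhd1, Slc5a1 and Palm3 were called without any single library.

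The lists higher in this comparison included the male-biased list (0.54 from all genes, 12 of 12 members, adjusted p = 1.72e-08, and 0.245 with an estimated correlation), drug and steroid metabolism (0.45, 18 of 19, adjusted p = 1.72e-08, and 0.584 with an estimated correlation) and organic anion, cation and urate transporters (0.33, 17 of 20, adjusted p = 1.22e-05, and 0.711 with an estimated correlation). The TCA cycle (0.20, 20 of 20, adjusted p = 0.000145) and NRF2 genes (0.24, 21 of 22, adjusted p = 0.000377) were higher and podocyte markers lower (−0.31, 5 of 8, adjusted p = 0.0214), each at 0.864 with an estimated correlation. Members past the threshold over the list alone numbered 9, 12, 7, 0, 7 and 0 in this order, with 1 member of drug and steroid metabolism lower. The TCA cycle lost its call without the 4 libraries with fewest genes (adjusted p = 0.109), and podocyte markers without vehicle sample 1 (0.0792) or dapagliflozin sample 3 (0.124), or with median-of-ratios scaling (0.15). Of 46 lists 13 passed, and 0 with an estimated correlation.

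In non-diabetic tubules dapagliflozin called 0 genes by limma in wild type (516 at an unadjusted p under 0.05, median of all genes −0.13). The lowest by rank were the signal peptidase gene Spcs2 (−1.06 ± 0.25), Slc22a23 (−1.16 ± 0.33) and Eapp (−1.18 ± 0.34), below the vehicle median in 4 of 4 samples at an adjusted p of 0.981. Antigen presentation genes were lower (−0.58 from all genes, 15 of 15 members, adjusted p = 0.00105), as were fatty acid synthesis (−0.30, 12 of 13, adjusted p = 0.00519) and nuclear-encoded oxidative phosphorylation (−0.16, 51 of 52, adjusted p = 0.000957), and podocyte markers were higher (0.36, 7 of 8, adjusted p = 0.00182). With an estimated correlation the adjusted p was 0.828 for each, and over the list alone 0 members were called. Antigen presentation lost its call without vehicle sample 6 (−0.20, adjusted p = 0.848), and oxidative phosphorylation (−0.02, adjusted p = 0.578) and podocyte markers (−0.08, adjusted p = 0.688) lost theirs without dapagliflozin sample 2. Oxidative phosphorylation also lost it with median-of-ratios scaling (adjusted p = 0.0707). In knockouts 1 gene was called by limma (494 at an unadjusted p under 0.05), the transcription factor gene Sox5, which fell by 1.39 ± 0.26 (adjusted p = 0.0259, 6 of 6 samples). It lost its call in 9 of 11 fits without 1 library, those without vehicle samples 1, 2, 3 or 6 or dapagliflozin samples 1, 2, 4, 5 or 6 (adjusted p up to 0.301). The call was also lost with median-of-ratios scaling (adjusted p = 0.158). The steroid dehydrogenase Hsd3b4 was at 2.85 ± 0.82 (5 of 6 higher) and complement C3 at −1.4 ± 0.42 (6 of 6 lower), both at an adjusted p of 1. There, endothelial markers (−0.37, 11 of 11, adjusted p = 0.000579) and stromal, mesangial and smooth muscle markers (−0.42, 12 of 12, adjusted p = 0.00174) were lower and fatty acid oxidation higher (0.21, 21 of 25, adjusted p = 0.00139), each at 0.715 with an estimated correlation and with 0 members over the list alone. The preset test passed 14 lists in wild type and 21 in knockouts, and the estimated one 0 in both. The average over genotypes, chosen after the data were seen, called 0 genes by limma (470 at an unadjusted p under 0.05) and passed 5 lists, and 0 with an estimated correlation.

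Whether dapagliflozin acted differently in Akita and non-diabetic wild-type tubules was tested as an interaction, which called 0 genes by limma (1423 at an unadjusted p under 0.05, median of all genes 0.32). As lists, the male-biased genes (0.82 from all genes, 12 of 12 members, adjusted p = 2.75e-08, and 0.47 with an estimated correlation) and drug and steroid metabolism (0.81, 18 of 19, adjusted p = 5.05e-07), fatty acid oxidation (0.44, 25 of 25, adjusted p = 7.46e-07) and organic anion, cation and urate transport (0.44, 19 of 20, adjusted p = 0.000121), each at 0.799 with an estimated correlation, were higher in the Akita response. Podocyte markers were lower (−0.70, 6 of 8, adjusted p = 2.92e-05, and 0.565 with an estimated correlation), a call lost without non-diabetic dapagliflozin sample 2 (−0.27, adjusted p = 0.132). Over the list alone 9, 12, 11, 5 and 0 members were called in this order. With quantile normalization the value was 0.50 for drug and steroid metabolism, 0.28 for fatty acid oxidation and 0.20 for organic transport. With no filter the last 2 were at 0.71 and 0.68. Podocyte markers ranged from −0.46 with no filter to −1.22 with a pseudocount of 0.1. Of 46 lists 14 passed, and 0 with an estimated correlation. Without Akita dapagliflozin sample 5 the interaction called 1 gene. The non-diabetic wild-type dapagliflozin group held 4 samples. There, mean TPM with vehicle and dapagliflozin was 1852 and 1644 for Kap, 59.2 and 39.0 for Cyp4a12a, and 177 and 158 for Cyp2e1. In non-diabetic knockouts, which are not part of this interaction, the means ran the other way (1738 and 1994, 55.4 and 64.6, and 168 and 211). None of these changes was called.

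Semaglutide in Akita wild-type tubules called 0 genes by limma (742 at an unadjusted p under 0.05, median of all genes 0.13). Capture numbers of the semaglutide (88 to 99) and vehicle samples (1 to 82) did not overlap. A drug effect could therefore not be told apart from one of capture order. The capture number as a covariate does not settle this, since its slope comes from the spread within groups. Cyp2e1 was at 141 ± 58.2 TPM (SD, n = 5) against 83.8 ± 34.4 with vehicle (n = 6), a log2 value of 0.75 ± 0.27 (adjusted p = 0.823, 5 of 5 samples above the vehicle median), and Slc7a13 at 0.82 ± 0.31 (adjusted p = 0.836, 4 of 5). The highest by rank were Arpp19 (0.91 ± 0.21, adjusted p = 0.539), the unfolded protein response factor Xbp1 (1.02 ± 0.27, adjusted p = 0.679) and Dzip1 (1.12 ± 0.30, adjusted p = 0.679), each in 5 of 5. The lowest were Ccnd1 (−1.04 ± 0.30, adjusted p = 0.775, 5 of 5), Palm3 (−0.81 ± 0.27, adjusted p = 0.801, 4 of 5) and the integrin Itgb6 (−0.84 ± 0.30, adjusted p = 0.823, 5 of 5). Higher lists were the male-biased genes (0.33 from all genes, 12 of 12 members), drug and steroid metabolism (0.31, 18 of 19) and S3 markers (0.49, 10 of 10), all at an adjusted p of 0.000622, organic anion, cation and urate transport (0.27, 18 of 20, adjusted p = 0.0014) and fatty acid oxidation (0.17, 24 of 25, adjusted p = 0.00273). Podocyte markers were lower (−0.32, 6 of 8, adjusted p = 0.0421). With an estimated correlation the adjusted p was 0.908 for each, and over the list alone 3 S3 markers and 0 members of the other lists were called. Without semaglutide sample 5 the value was 0.17 for the male-biased genes (adjusted p = 0.0458), 0.31 for S3 markers (0.0229) and 0.11 for fatty acid oxidation (0.0458). That of organic transport was 0.18 without vehicle sample 2 (adjusted p = 0.0083) and 0.16 with the capture number as a covariate (0.0293). Calls were lost for S3 markers without semaglutide sample 3 (0.27, adjusted p = 0.142), for drug and steroid metabolism without semaglutide sample 5 (adjusted p = 0.0584), for fatty acid oxidation without vehicle sample 2 (0.196) or the 4 libraries with fewest genes (0.577), and for podocyte markers without vehicle samples 1, 4 or 6 or semaglutide samples 2 or 4 (up to 0.163). Podocyte markers also lost theirs with median-of-ratios scaling (adjusted p = 0.21), as did drug and steroid metabolism with the capture number as a covariate (0.0804). Of 46 lists 9 passed, and 0 with an estimated correlation.

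Semaglutide and dapagliflozin, compared directly in Akita wild type, differed in 0 genes by limma (332 at an unadjusted p under 0.05). Their capture numbers did not overlap (88 to 99 and 4 to 78), so a difference between the drugs could not be told apart from one of capture order. Eif2b2 was at 1.19 ± 0.40 (5 of 5 samples above the dapagliflozin median), Rps6kb2 at −0.95 ± 0.32 and Pdlim2 at −0.96 ± 0.31 (5 of 5 below), at an adjusted p of 1. Nuclear-encoded oxidative phosphorylation was the 1 list that passed, lower with semaglutide (−0.13 from all genes, 50 of 52 members, 0 over the list alone, adjusted p = 0.000879, and 0.988 with an estimated correlation). It lost its call without semaglutide sample 3 (adjusted p = 0.0797) or dapagliflozin sample 1 (0.0964). The count was 1 without dapagliflozin sample 5.

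Across the 12742 genes, which are not independent replicates, the effect of diabetes in wild type correlated negatively with those of dapagliflozin (r = −0.54), semaglutide (r = −0.474) and Sglt1 knockout in Akita (r = −0.463), and dapagliflozin with semaglutide positively (r = 0.503). All 4 share the Akita wild-type vehicle libraries. In 1000 simulations of unchanged groups against shared libraries r averaged −0.443, −0.447, −0.473 and 0.441, with 95% of the first between −0.713 and −0.147. With those vehicle libraries split into 2 sets, 1 for each effect, r averaged −0.11, −0.0516, −0.0154 and 0.0637 over 20 splits. Covariances were −0.0525, −0.0443, −0.0392 and 0.0459, against simulated means of −0.0415, −0.0414, −0.0423 and 0.0405. Pairs with no shared library gave r = −0.0948 for diabetes in knockouts with dapagliflozin in wild type, −0.0497 for diabetes in knockouts with semaglutide, and 0.0848 for diabetes in wild type with diabetes in knockouts. All 3 lie within the simulated ranges (−0.368 to 0.346 for the first), and the second turned to 0.00452 without semaglutide sample 6.

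Some lists passed the preset test in none of the 18 comparisons. They were gluconeogenesis, PPAR-alpha targets and ketogenesis, tubular injury and dedifferentiation, mTOR and AMPK signalling, insulin and FOXO signalling, the circadian clock and collecting duct principal cell markers. The lowest adjusted p of the injury list, with 16 members tested, was 0.0606.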

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

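The 3 tests of the male-biased list and the test of strain sequence below were chosen only after their results had been seen, and the other tests were written down before. AI506816 was left out of the strain test because it had been seen to rank high in the knockout comparisons before that test was written. Among 126 groups of 4 to 6 libraries, over 14 quantities, 2 held a library far from the others, where chance alone flags about 1 in 20 groups. Slc5a1 was at 0.123 TPM in dapagliflozin sample 3 of the non-diabetic knockouts and at 0 in the other 5 (n = 6). Cyp4a12a was at 90.3 TPM in vehicle sample 5 of the non-diabetic knockouts and between 39.8 and 53.0 TPM in the other samples (n = 5).

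Some lists differed between groups in the interaction tests. They are those picked after the result was seen from the 14 and 15 that passed, and each missed the threshold with an estimated correlation. Relative to all genes, the response to dapagliflozin in wild type was higher in Akita than in non-diabetic tubules for the male-biased list (0.82), drug and steroid metabolism (0.81), fatty acid oxidation (0.44) and organic anion, cation and urate transport (0.44), and lower for podocyte markers (−0.70), values that moved to between 0.20 and 0.68 for organic transport, 0.28 and 0.71 for fatty acid oxidation and −0.46 and −1.22 for podocyte markers in other settings, and to 0.50 for drug and steroid metabolism. The podocyte call in this response was lost without non-diabetic dapagliflozin sample 2. These values are for wild type alone, where the non-diabetic dapagliflozin group held 4 samples, and do not show whether knockouts differ in the same way. The signed change with diabetes was higher in knockouts than in wild type for thick ascending limb markers (0.73, and 0.45 to 1.22 in other settings) and the male-biased list (0.45). Thick ascending limb markers were lower with diabetes in wild type. The male-biased list was lower with diabetes in both genotypes, so that its fall was smaller in knockouts. Its call was lost without the 4 libraries with fewest genes. The signed change was lower in knockouts for podocyte markers (−0.46, and −0.92 with a pseudocount of 0.1) and immediate early and heat shock genes (−0.40). The last value was −0.23 without non-diabetic wild-type vehicle sample 4.

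The male-biased list was lower in Akita vehicle tubules and higher in Akita tubules with dapagliflozin, though averaged over genotypes neither passed with an estimated correlation (adjusted p = 0.133 and 0.251). A TPM scale set by ribosomal RNA is argued against as the whole cause of the change with diabetes, since the members' mean, not centred on all genes, was still −0.55 (95% interval −0.78 to −0.33) after rescaling to nuclear protein-coding genes, against −0.71 before, while the median of all genes went from −0.20 to −0.00738. For diabetes averaged over genotypes, the list median less that of all genes was −0.55 without the 4 libraries with fewest genes and −0.57 with them. The adjusted p of camera without them was 5.17e-10, and 0.167 with an estimated correlation. This argues against those libraries as the cause of the size of the change with diabetes. The test did not cover the rise with dapagliflozin, for which the 4 libraries are vehicle samples. Tubules were picked by staining for SGLT2, a marker of the early tubule. Even so, capture of fewer late (S3) tubule cells could not be told apart from a change within cells. The 7 S3 markers outside the list moved by −0.56 and the list by −0.77, a difference of 0.21 (95% bootstrap interval −0.26 to 0.47). Unlike the 95% interval above, which is over libraries, this one resampled genes and holds no spread between libraries. A biological explanation, diabetes itself and its treatment by dapagliflozin, may apply as well. For diabetes or dapagliflozin in wild type the list had no larger change in 99 other groupings (1 of 100 in each, the real grouping). Both comparisons use the same 6 Akita wild-type vehicle samples. Low chance values there would give both the fall and the rise, so the counts are not separate evidence. The list median less that of all genes was −0.34 with diabetes in knockouts and 0.60 with dapagliflozin in wild type, which share no sample. It was −0.75 with diabetes in wild type and 0.32 with dapagliflozin in knockouts, which share none either. The call for diabetes in knockouts was lost without some single libraries.

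Abhd1 was higher in the knockouts of every background. Gm43694 was called as lower in the average over 4 backgrounds. Of the vehicle comparisons tested alone, it was called in non-diabetic tubules and not in Akita. Reads of the overlapping gene Preb are unlikely to be the cause, since Preb itself was at 0.10 (95% interval −0.11 to 0.31). Sequence of the strain used for targeting, kept around Slc5a1, could be the cause, and 11 of 133 other genes within 10 Mb (8.27%) had a p under 0.05, against 4.81% of 12006 elsewhere (exact p = 0.0579 by the 1-sided Fisher's test, or 0.0295 with AI506816 kept), which leaves this open. Loss of SGLT1 itself could not be told from the locus, since 0 libraries had a level of Slc5a1 against their label. Both explanations remain open.

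The effects of diabetes and of dapagliflozin or semaglutide ran in opposite directions over all genes in Akita wild type. Chance values of the shared vehicle libraries may account for this, since r was −0.0948 between diabetes in knockouts and dapagliflozin in wild type, which share no library. Libraries differing in genes detected could not be judged as a cause, since r was −0.548 with the number of genes as a covariate while r without it already lay within the simulated range. A true opposing effect of the drugs beneath the shared chance values is not excluded by these tests.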

How the results depend on the processing

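Rescaling to nuclear protein-coding genes and fits without the 4 libraries with fewest genes were chosen only after the data were seen. So was median-of-ratios scaling with an estimated correlation. No paired analysis was possible because the labels tie no samples across groups. TPM holds no depth, so how far depth limits low genes such as Slc5a1 is unknown. Where no reason is given below, the cause was not tested. Of 131 gene results, 130 stayed the same with a pseudocount of 0.1, 117 with sample weights and 110 with the capture number as a covariate. With genes detected as a covariate 98 did, 94 with quantile and 91 with median-of-ratios scaling (31 weaker). Without the 4 libraries with fewest genes 80 did (49 weaker). With no filter 85 stayed the same and 46 were weaker. With the stricter filter, which tested 116 of the 131, 113 stayed the same and 3 were stronger. These counts include genes not called that stayed so, and are not numbers of calls kept. Lists were not run with sample weights or in fits of only the groups compared. Of 71 list results, 63 to 70 stayed the same in the other settings just named, but 1 with an estimated correlation, and 12 where it was combined with median-of-ratios scaling. With no filter 67 stayed the same, 3 were weaker and 1 was reversed. With the stricter filter 51 of 64 stayed the same and 13 were weaker.

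Numbers of called genes that moved by over 1.5 times are given by setting, against main counts of 3 for diabetes in wild type, 71 for diabetes averaged over genotypes, 3 and 2 for Sglt1 knockout in non-diabetic and Akita tubules, 3 for the knockout averaged over backgrounds, 8 for knockout with dapagliflozin, 1 for dapagliflozin in non-diabetic knockouts, 104 for dapagliflozin in Akita averaged over genotypes, and 0 otherwise. With a pseudocount of 0.1, knockout with dapagliflozin had 20 and dapagliflozin in non-diabetic knockouts 0. With no filter the counts were 0 for diabetes in wild type, 18 for diabetes averaged, 4 for knockout with dapagliflozin, 0 for dapagliflozin in non-diabetic knockouts, 1 for dapagliflozin in Akita wild type and 6 for dapagliflozin in Akita averaged. With the stricter filter, under which fewer genes were tested and Slc5a1 and Gm43694 were not among them, they were 6 for diabetes in wild type, 128 for diabetes averaged, 1 for each of the 3 knockout comparisons, 0 for dapagliflozin in non-diabetic knockouts and 233 for dapagliflozin in Akita averaged.

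In the next 3 settings dapagliflozin in non-diabetic knockouts had 0. Quantile normalization gave 8 for diabetes in wild type, 25 for diabetes averaged, 6 for the averaged knockout, 53 for knockout with dapagliflozin, 2 for dapagliflozin in Akita knockouts and 58 for dapagliflozin in Akita averaged. Median-of-ratios scaling gave 12, 22, 5, 44, 3 and 54 in the same order. TPM rescaled to nuclear protein-coding genes gave 11 for diabetes in wild type, 31 for diabetes averaged, 45 for knockout with dapagliflozin, and 2 each for dapagliflozin in Akita wild type and knockouts. In fits of only the groups compared, which use fewer samples, counts were 6 for diabetes in wild type, 30 for diabetes averaged, 1 and 0 for dapagliflozin in non-diabetic wild type and knockouts, and 3 for dapagliflozin in Akita averaged. Sample weights (limma) gave 38 for diabetes in wild type, 719 for diabetes averaged, 5 for the non-diabetic knockout, 20 for knockout with dapagliflozin, 9 for dapagliflozin in Akita wild type, 426 for its average and 6 for its interaction with diabetes. The capture number as a covariate gave 1 for diabetes in wild type and 17 averaged. The number of genes detected as a covariate gave 9 for diabetes averaged, 31 for knockout with dapagliflozin and 34 for dapagliflozin in Akita averaged. Without the 4 libraries with fewest genes the counts were 1 for diabetes in wild type, 4 averaged, 4 for knockout with dapagliflozin and 0 for dapagliflozin in Akita averaged.

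Leaving out each library in turn gave 0 to 6 for diabetes in wild type, 0 to 1 in knockouts and 11 to 313 averaged. It gave 3 to 5 for the averaged knockout and 3 to 26 for knockout with dapagliflozin. For dapagliflozin the ranges were 0 to 1 in non-diabetic knockouts, 0 to 5 in Akita wild type, 0 to 1 in Akita knockouts, 9 to 378 averaged over the Akita genotypes and 0 to 1 for the interaction with diabetes. Semaglutide less dapagliflozin had 0 to 1.

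Some values near 0 turned their sign. Slc5a2 with diabetes in knockouts (−0.14) was 0.11 with quantile normalization, 0.21 with median-of-ratios scaling, 0.23 with genes detected as a covariate, 0.20 when rescaled to nuclear protein-coding genes and 0.0359 without the 4 libraries. With diabetes averaged it was 0.01, and −0.0446 to 0.084 as single libraries were left out. Other scalings moved it further from 0, up to 0.36 there and from 0.15 to 0.61 with diabetes in wild type, both with quantile normalization. With dapagliflozin in Akita it went from −0.41 to −0.83 in wild type with that normalization, and averaged over genotypes from −0.30 to as low as −0.64, a call gained with all 3 other scalings. Slc5a2 in the averaged knockout (0.08) was −0.0132 with median-of-ratios and −0.00873 with nuclear protein-coding scaling. Slc2a2 there (0.05) was −0.032 with quantile, −0.0381 with median-of-ratios and −0.0367 with nuclear protein-coding scaling, −0.000466 with genes detected as a covariate, and −0.0103 to 0.108 with single libraries left out. Glucose transport there (−0.03) was 0.0282 with no filter, and −0.0511 to 0.000129 with single libraries left out. Fatty acid synthesis with diabetes averaged (−0.12) was 0.00193 with genes detected as a covariate. Podocyte markers with dapagliflozin in non-diabetic wild type (0.36) ran from −0.0752 to 0.557, and the correlation of diabetes in knockouts with semaglutide (−0.0497) from −0.083 to 0.00452.

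Some list values (median less all genes) kept their call but moved by over 1.5 times. They became larger for 14 results with a pseudocount of 0.1, 19 with no filter, 3 with the stricter filter and 8 with nuclear rescaling. They became smaller for 10 with quantile normalization, 5 with no filter, 3 with median-of-ratios scaling, 2 with nuclear rescaling and 2 with genes detected as a covariate. The capture number and leaving out the 4 libraries gave 1 of each. The TCA cycle with dapagliflozin in Akita averaged (0.20) was at 0.13 with median-of-ratios scaling and 0.11 without the 4 libraries.

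Single libraries moved these list values by over 1.5 times with the call kept, besides those of glucose transport. Immediate early and heat shock genes were at −0.16 with diabetes in knockouts (−0.37) without non-diabetic knockout vehicle sample 2, and at −0.23 in the interaction of diabetes with knockout (−0.40) without non-diabetic wild-type vehicle sample 4. With semaglutide, the male-biased list (0.33) was at 0.17, S3 markers (0.49) at 0.31 and fatty acid oxidation (0.17) at 0.11 without semaglutide sample 5, and organic transport (0.27) at 0.18 without vehicle sample 2. The renin-angiotensin system with dapagliflozin in Akita averaged (0.23) was at 0.12 without wild-type dapagliflozin sample 5 and 0.14 without knockout dapagliflozin sample 4. With diabetes in wild type, organic transport (−0.22) was at −0.15 without Akita vehicle sample 2 and fatty acid synthesis (−0.27) at −0.18 without Akita vehicle sample 5. The latter averaged over genotypes (−0.12) was at −0.20 without non-diabetic knockout vehicle sample 1 and −0.18 without Akita knockout vehicle sample 1. With dapagliflozin in non-diabetic wild type, fatty acid synthesis (−0.30) was at −0.17 without dapagliflozin sample 2, and oxidative phosphorylation (−0.16) at −0.24 and podocyte markers (0.36) at 0.56 without dapagliflozin sample 5. With dapagliflozin in Akita, NRF2 genes were at 0.11 in wild type (0.17) without vehicle sample 2 and at 0.28 in knockouts (0.18) without knockout dapagliflozin sample 3, and organic transport in knockouts (0.18) at 0.12 without knockout dapagliflozin sample 5.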

Other observations

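The counts over other groupings were planned before the data were seen, but those of the 4 averages follow comparisons chosen only afterwards. The samples of each comparison were divided into groups of the same sizes in 100 ways, the real one included, and limma was run on each. For diabetes, the real number of called genes was reached in 1 of 100 in wild type (3 genes, at most 2 in any other), in 100 in knockouts (0 genes, up to 1275) and in 4 for the average (71 genes, up to 6429). For Sglt1 knockout it was reached in 1 in non-diabetic tubules (3 genes, at most 1), in 5 in Akita (2 genes, up to 886), in 3 for the average (3 genes, up to 89) and in 2 for knockout with dapagliflozin (8 genes, up to 126). For dapagliflozin it was reached in 100 in non-diabetic wild type (0 genes, up to 2), in 2 in non-diabetic knockouts (1 gene, at most 1), in 100 for their average (0 genes, up to 2), in 100 in Akita wild type (0 genes, up to 2), in 100 in Akita knockouts (0 genes, up to 3216) and in 1 for the Akita average (104 genes, at most 24). For semaglutide it was reached in 100 (0 genes, up to 1), and in 100 for its difference from dapagliflozin (0 genes, up to 2). For the interactions it was reached in 100 each, all with 0 genes, with up to 412 for dapagliflozin with diabetes, 927 for diabetes with knockout and 497 for dapagliflozin with knockout. Other groupings with far more calls than the real one show that libraries differ in ways apart from the labelled groups.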
